A study of Rattus norvegicus with 6 samples.

How the data were processed

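RNA of 3 reflux-induced rat esophageal tumor cell lines (JA, JB and Amy) was compared with an equal mixture of 2 normal rat esophageal cell lines on 2-colour cDNA arrays, 2 arrays per line. Per the labels, the line was labelled with Cy3 and the pool with Cy5 on 1 array of each pair and the dyes were exchanged on the other, so each pair is a technical dye swap.

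The deposited values were log ratios, 1 per spot and array, used here as log2 ratios. Scanner, background correction, normalization and spot filter were not given in the sources used here, and no spot intensities were used. The log base was not stated; the lowest value, -12.7, would exceed the range of a scanner in base 10 or natural logarithms. The arrays of a pair correlated at 0.816 in JA, 0.791 in JB and 0.867 in Amy over all spots, which fits ratios already in a common direction, and no sign was changed. After the mean of the 3 arrays of a dye orientation was subtracted, the deviations of a line correlated at 0.340 to 0.465 between its 2 arrays, and those of different lines at -0.29 to -0.04. The replicate number of an array is its dye orientation per the labels, and the difference between the 2 orientations correlated between lines at 0.613 for JA and JB, 0.552 for JA and Amy and 0.526 for JB and Amy, so the numbers pair the arrays. That the common direction is line over pool was taken from the order of the names in the sample titles. Array medians were -0.11 and -0.15 for JA, -0.05 and -0.12 for JB, and -0.13 and -0.13 for Amy (line in Cy3, line in Cy5), so the centring is not exact and its method is unknown.

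Of 16128 spots, 8084 carried 1 gene symbol, 40 several and 8004 none in the platform annotation; 8076 were matched by gene identifier to the RefSeq genes of assembly GRCr8, which changed 0 symbols. Adjacent spots formed 8064 clones. A feature was a gene, as the mean over its spots, or a clone without a single symbol. The first 2 clones of the 655 genes with several clones correlated at 0.553, against a mean of -0.0067 for random pairs of clones.

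The 2 arrays of a line were averaged, which cancels the dye effect, and each line entered as 1 replicate. The mean of the 3 lines was tested against 0 with limma 3.58.1 (lmFit and eBayes, intercept only) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over 7180 features and a threshold of 0.05. The pool is 1 control sample and its own spread is left out of the test. Differences of single lines have no replicate and were described by a size of at least 1 on the log2 scale on both arrays, or, between lines, against both other lines within each dye orientation. No low-value filter was applied. Correlations between lines were set beside 100 simulated draws in which lines with no change shared a pool with the variance of a mean of 2 lines.

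The 25 gene lists, the rule for named genes and the tests were set before the data were examined. Of the symbols on the lists, 396 were measured. The 22 lists with at least 5 measured members were tested with camera (inter-gene correlation 0.01, Benjamini-Hochberg over the lists); the 3 others were described. Single-line shifts of a list were placed among 10000 random lists. Genes named were the 12 with the highest and the 12 with the lowest mean among genes that passed with 1 sign on all 6 arrays, up to 5 per direction that set a line apart, up to 4 per list with the largest mean and 1 sign on all arrays, all members of lists too short to test, and 4 measured genes of a fixed set (Ccnd1, Erbb2, Krt8, Actb). Fen1, Pcna, Ccnb2, Aurkb, Col6a2, Fn1, Eln, Pdgfra, Csf1r, Tyrobp, Cd3e and Cd53 were added to the lists' accounts after their values were seen. The order and wording of all examples were also chosen then.

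In data simulated for the comparison of the 3 lines with the pool over 7180 features, log2 changes of 0.25, 0.5, 1 and 2 were recovered at 0%, 8%, 92% and 100% (50 features each), with 12 false among 112 calls (10.7%). Over 100 draws the false share averaged 8.4%, from 2.0% to 19.1%, above the 5% that the threshold sets. Only 200 features were changed in the simulation, against 3843 called in the data. The lines were drawn independently, with no error of a shared pool. Neither the recovery nor the false share therefore carries over directly. Alternatives were arrays centred on the median, scaled to a common spread or quantile normalized, line as a random block, a spread for the pool, robust and unmoderated variances, single clones, a filter on dye-swap disagreement, each dye orientation alone, lines and arrays left out, other thresholds, an estimated correlation, fry and, added later, tissue marker features left out and the replicate number as a block. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.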

Results

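Gene expression was compared between 3 rat esophageal tumor cell lines, JA, JB and Amy, and an equal mixture of 2 normal rat esophageal cell lines. The tumor lines came from tumors induced by reflux, the backflow of stomach contents into the esophagus. Each line was hybridized with the normal pool on 2 cDNA arrays with the dyes exchanged, giving 6 arrays of 16128 spots with no missing value. The 8064 clones on the array, each printed as a pair of spots, gave 7180 features, of which 3158 were named genes and 4022 were clones without a single gene name. The values were log ratios, written here as tumor line over normal pool. That direction is likely rather than settled: the sample titles name the line first and the pool second, and turning all signs would only exchange higher and lower throughout. The log base was not stated and was taken as 2. Array medians lay between -0.05 and -0.15. Duplicate spots correlated at 0.907 to 0.949 within an array, and the dye-swapped arrays of a line correlated at 0.844 in JA, 0.815 in JB and 0.888 in Amy across features. The 2 arrays of a line are a technical dye swap, so each line counted as 1 replicate and the number of lines limits the precision.

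The first comparison asked which genes the 3 tumor lines had in common as higher or lower than normal esophageal cells. The highest named gene was Nppb, which encodes the B-type natriuretic peptide precursor, with a mean log2 ratio of 6.01 ± 0.35 (SD, n = 3 lines), or 64.3-fold. Regulators of cell division were also among the 12 highest: cyclin E1 (Ccne1) at 3.08 ± 0.53, the mitotic kinase Plk1 at 2.97 ± 0.29, the cyclin-dependent kinase Cdk1 at 2.91 ± 0.47 and Cdc20, an activator of the anaphase-promoting complex, at 2.71 ± 0.24. The lowest were 2 genes of connective tissue matrix, decorin (Dcn) at -9.00 ± 0.53 and the type I collagen chain Col1a2 at -8.90 ± 0.46. Galectin-7 (Lgals7), a lectin of stratified epithelia, was lower at -5.82 ± 1.01. All of these had 1 sign on all 6 arrays, and their adjusted p in limma lay between 4.34e-05 and 5.79e-04.

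The other genes among the 12 highest were the nucleotidase Bpnt1 at 4.33 ± 0.90, the LIM-domain transcription regulator Lmo1 at 4.16 ± 0.12, the actin-nucleation subunit Arpc1b at 3.55 ± 0.59, aldose reductase (Akr1b1) at 3.21 ± 0.54, the tetraspanin Tspan8 at 3.14 ± 0.37, proenkephalin (Penk) at 2.96 ± 0.45 and the sodium-glucose cotransporter Slc5a2 at 2.86 ± 0.89. Among the 12 lowest, the fatty acid receptor Cd36 stood at -7.36 ± 0.88, Srpx at -7.26 ± 0.63 and the growth factor midkine (Mdk) at -6.82 ± 0.34. The calcineurin regulator Rcan2 followed at -6.66 ± 0.42, the retinoic acid binding protein Crabp2 at -6.23 ± 0.27 and the NF-kappaB signaling adaptor Bcl10 at -5.89 ± 0.86. Igfbp6, which binds insulin-like growth factors, stood at -5.55 ± 0.63, the ectonucleotidase Entpd1 at -5.45 ± 0.07 and the scavenger receptor Colec12 at -5.45 ± 0.57. Most of the 12 highest and 12 lowest genes, Nppb among them, were measured by 1 clone. The SD over lines does not cover differences between clones of a gene. The 2 clones of Akr1b1 differed, at 0.96 and 5.47, and those of Dcn stood at -10.17 and -7.83. No spot intensities were used here, so the largest of these ratios cannot be told from bounds set by a dim channel.

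**Figure D1:**
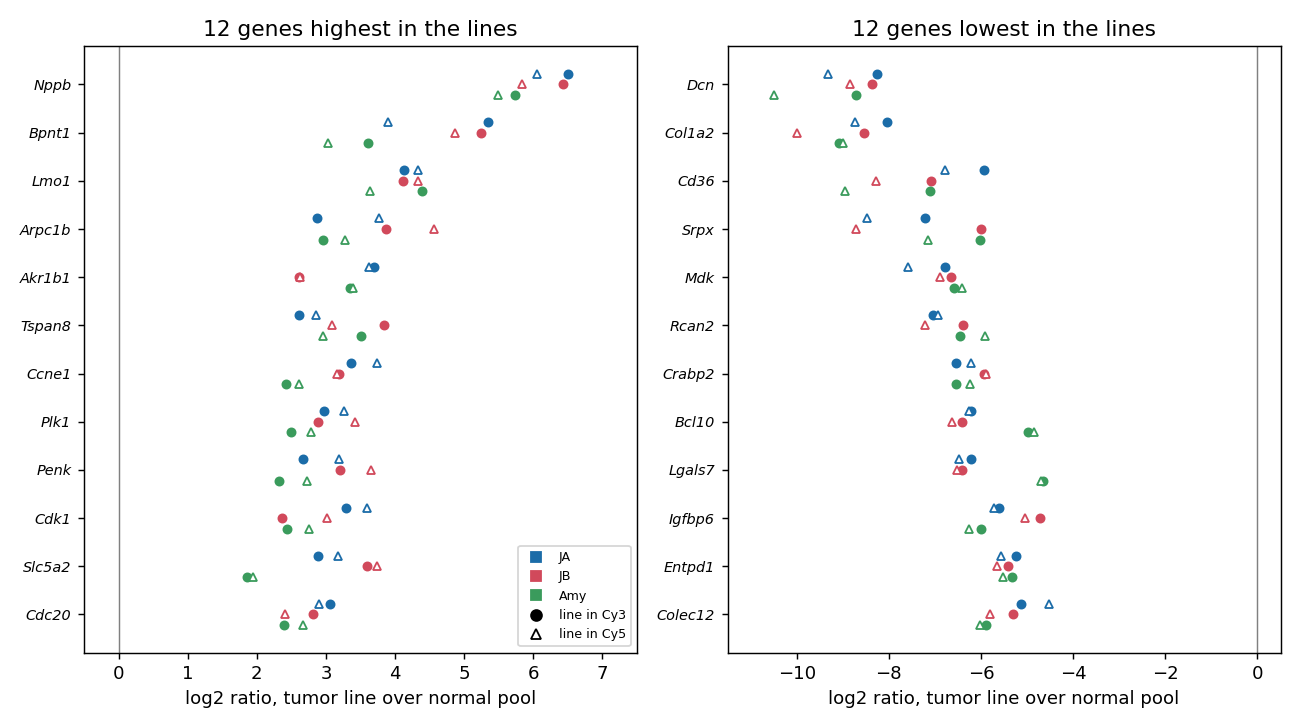
Log2 ratio of tumor line over normal pool (horizontal axis) on each of the 6 arrays for the 12 named genes with the highest and the 12 with the lowest mean. Colour marks the line, circles are arrays with the line in Cy3 and triangles arrays with the line in Cy5; Nppb has the highest mean, 6.01, and Dcn the lowest, -9.00.

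Of 7180 features, 3843 passed the test at an adjusted p under 0.05 (limma), 1487 higher and 2356 lower in the tumor lines. Among named genes, 731 were higher and 1009 lower. The median of all features was -0.12, and with each array centred on its median the split was 1844 higher and 1981 lower. A 2-fold ratio of one sign on all 6 arrays was reached by 203 features above and 583 below. Means of -4 or lower were seen for 91 features and means of 4 or higher for 3. The test takes the pool as a single sample and leaves out its own spread; when the pool was given the spread of a mean of 2 lines, 1970 features passed. The count was 2076 without JA, 3698 without JB and 2701 without Amy, and a test without moderation of the variances called 1040. The p-values measure the spread between these lines only. In simulated data with 200 of 7180 features changed, the share of false calls at this threshold averaged 8.4%. That share depends on how many features change, and far more were called here. The simulated lines were also drawn without the error of a shared pool, which the real ratios carry. The error among the calls is therefore not known and may lie above 5%.

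Most measured genes of the cell cycle and DNA replication list were higher in the tumor lines. Of 25 measured members, 20 were higher, 2 were lower and 3 did not pass, with a median of 1.23 (camera adjusted p = 7.73e-07). With a correlation between genes estimated from the data, the camera adjusted p was 0.854 and the call was lost. That version of camera takes its degrees of freedom from the 3 lines. Its loss therefore does not show that correlation between genes removes the call. However, the estimate was 0.272, above the preset 0.01, so the first adjusted p may be too small. Beyond the mitotic regulators above, cyclin D1 (Ccnd1) stood at 1.39 ± 0.10 (adjusted p = 9.07e-04), and was higher in all 3 lines. The replication genes Rfc4, Fen1 and Pcna were higher at 2.11 ± 0.74, 2.02 ± 0.32 and 1.03 ± 0.46. The 2 that fell were cyclin B2 (Ccnb2) at -1.81 ± 0.50 and the mitotic kinase Aurkb at -0.55 ± 0.08. Adjusted over the list alone, 23 members passed.

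Genes of the proteasome and its assembly were the other list called higher: 6 of 17 rose, none fell and the median was 0.35 (camera adjusted p = 0.00487). The call was lost with an estimated correlation (adjusted p = 0.890) and on the arrays with the tumor line in Cy3 (adjusted p = 0.0506). Psmd2 stood at 1.28 ± 0.31, the assembly factor Psmg1 at 1.06 ± 0.35 Psmd1 at 0.77 ± 0.18 and Psmd8 at 0.65 ± 0.05. Adjusted over the list alone, 6 passed.

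Genes of fibroblasts and the extracellular matrix were lower as a group. Of 20 measured members, 18 fell, the type VI collagen chain Col6a2 rose to 1.06 ± 0.31 and fibronectin (Fn1), at 0.53 ± 0.68, did not pass; the median was -3.10 (camera adjusted p = 1.69e-06). The call was lost with an estimated correlation (adjusted p = 0.854). Besides Dcn and Col1a2, the fibrillar collagens Col3a1 and Col1a1 stood at -5.39 ± 0.03 and -4.44 ± 0.06. Between dye orientations Col1a1 differed more, at -3.99 with the line in Cy3 and -4.90 in Cy5. The matrix proteins Sparc and elastin (Eln) stood at -4.18 ± 0.89 and -3.02 ± 0.30, and the receptor Pdgfra at -2.81 ± 0.29. Adjusted over the list alone, 19 passed.

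Most measured markers of leukocytes, muscle and endothelium were lower as well. In the leukocyte list 9 of 11 measured genes were lower, Tyrobp was higher and 1 did not pass, with a median of -2.48 (camera adjusted p = 0.00655; 0.854 as the adjusted p with an estimated correlation). The MHC class II genes RT1-Ba, RT1-Db1 and Cd74 stood at -5.22 ± 0.26, -4.93 ± 0.37 and -3.86 ± 0.42, the T-cell coreceptor Cd4 at -4.06 ± 0.41 and the macrophage receptor Csf1r at -3.57 ± 0.11. The T-cell gene Cd3e and Cd53 fell far less, to -0.45 ± 0.06 and -0.48 ± 0.20. In the smooth and skeletal muscle list 6 of 8 were lower, none was higher and the median was -1.60 (camera adjusted p = 0.0251; adjusted p = 0.854 with an estimated correlation). The sarcomeric light chain Myl11 stood at -5.11 ± 0.15 and the intermediate filament desmin (Des) at -4.87 ± 0.13, followed by the light chain Myl1 at -2.50 ± 0.08 and the tropomyosin Tpm1 at -1.82 ± 1.15 (adjusted p = 0.0188), whose call was lost without JA (0.124) or Amy (0.0907). The 2 clones of Tpm1 stood at -3.01 and -0.63 and those of Myl1 at -3.35 and -1.64. The test of the muscle list was lost without moderation of the variances (adjusted p = 0.084). All 3 measured endothelial genes were lower, Kdr at -2.39 ± 0.27, Emcn at -1.53 ± 0.12 and Tie1 at -1.16 ± 0.12, a list too short to test. The SD is over line means, in which the dyes are averaged. Emcn itself averaged -0.84 on the arrays with the line in Cy3 and -2.22 in Cy5, and its clones stood at -1.97 and -1.08. Adjusted over the list alone, 10 leukocyte, 6 muscle and 3 endothelial genes passed. The 2 clones of RT1-Db1 stood at -6.71 and -3.15.

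Few markers of epithelial identity were measured as named genes. Of the squamous list only Lgals7 and cystatin B (Cstb) were measured, and both passed, also when adjusted over the list alone. Cstb, at -0.68 ± 0.46 (adjusted p = 0.0364), no longer passed without JA (adjusted p = 0.181), without JB (0.0742) or with centred arrays (0.0671). In the list of columnar and intestinal epithelium 1 of 7 genes rose, Tspan8, and 4 fell, among them clusterin (Clu) at -3.14 ± 0.70 and the gastric protease cathepsin E (Ctse) at -1.61 ± 0.42 and the apolipoprotein Apoa4 at -1.32 ± 0.34; the list did not pass (median -0.76, adjusted p = 0.681), and 5 passed over the list alone. In the epithelial adhesion list P-cadherin (Cdh3) rose to 1.98 ± 0.15 and alpha-catenin (Ctnna1) to 0.72 ± 0.40 while Cd24 fell to -3.58 ± 1.30 and the desmosomal plakophilin Pkp2 to -0.77 ± 0.23, with 3 of 9 higher, 2 lower, 5 over the list alone and a list adjusted p of 0.439 (median 0.27). The call of Ctnna1 was lost without JA (adjusted p = 0.0780) or Amy (0.0554), and that of Pkp2 without JA (0.0576). Keratin 8 (Krt8) stood at 0.41 ± 0.40 (adjusted p = 0.111) and passed on the arrays with the line in Cy5 (0.0364). The receptor Erbb2 stood at 0.01 ± 0.35 (adjusted p = 0.947), its 2 clones at -0.32 and 0.35. Beta-actin (Actb) stood at 0.73 ± 0.38 (adjusted p = 0.0200); it did not pass without JA (0.0958), without Amy (0.0852), on the arrays with the line in Cy3 (0.210) or without the JB array with the line in Cy5 (0.179).

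The remaining tested lists held genes that moved both ways, and none passed in camera. The growth factor and receptor list had 7 higher and 12 lower of 30 (20 over the list alone, median -0.08, adjusted p = 0.890), with the binding proteins Igfbp4 and Igfbp5 at -4.32 ± 0.31 and -3.27 ± 0.70 and Igf2 at -3.40 ± 0.39. Glycolysis and hypoxia had 7 higher and 7 lower of 18 (15 over the list alone, median 0.21, adjusted p = 0.439), with Hif1a, the oxygen-regulated transcription factor, at 2.58 ± 0.24 and Bnip3, a mitochondrial protein of cell death, at -4.52 ± 0.26, the collagen lysyl hydroxylase Plod2 at -4.26 ± 0.34 and the pyruvate kinase Pklr at -1.99 ± 0.32. Oxidative stress and glutathione had 9 higher and 10 lower of 28 (20 over the list alone, median 0.02, adjusted p = 0.720), with glutathione synthetase (Gss) at 2.32 ± 0.24 and the extracellular dismutase Sod3 at -3.65 ± 0.14, and the glutathione transferases Gstm2 and Gstm7 at -2.88 ± 0.57 and -2.56 ± 0.16. The p53 target list had 3 higher and 3 lower of 11 (7 over the list alone, median 0.08, adjusted p = 0.893), with Sesn1 at -4.04 ± 0.27, Gadd45g at -1.67 ± 0.41 and the kinase Plk2 at 0.97 ± 0.38, a call lost without JA (0.0665) or Amy (0.0508). Apoptosis had 4 higher and 4 lower of 13 (9 over the list alone, median -0.05, adjusted p = 0.847), with Aifm1 at 1.999 ± 0.31 and the death receptor Fas at -1.69 ± 0.50, and the survival protein Mcl1 at -0.90 ± 0.05.

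Proteases and inhibitors had 3 higher and 8 lower of 18 (11 over the list alone, median -0.29, adjusted p = 0.681), with the metalloprotease inhibitor Reck at -4.20 ± 0.23 and cathepsin K (Ctsk) at -3.84 ± 0.33, followed by the metalloprotease Mmp23 at -1.98 ± 0.26 and cathepsin L (Ctsl) at -1.92 ± 0.88, a call lost without JA (0.0664). Mesenchymal transition had 2 higher and 4 lower of 11 (6 over the list alone, median -0.16, adjusted p = 0.439) and shared 5 genes with the fibroblast list. Interferon response and MHC class I had 2 higher and 7 lower of 22 (7 over the list alone, median -0.37, adjusted p = 0.388), with Ifit2 at -2.63 ± 0.57, Ifi27l2b at -2.12 ± 0.35, the transcription factor Irf9 at -1.37 ± 0.17 and Ifitm1 at -1.002 ± 0.11. Irf9 averaged -0.77 with the line in Cy3 and -1.97 in Cy5, a difference that the SD of line means leaves out. Inflammation and prostaglandin synthesis had 1 higher and 7 lower of 15 (8 over the list alone, median -0.10, adjusted p = 0.681), with the alarmin Il33 at -3.51 ± 0.30, the cytokine receptor subunit Il6st at -1.23 ± 0.07 and the adhesion molecule Vcam1 at -0.83 ± 0.10. Cholesterol and fatty acid synthesis had 4 higher and 7 lower of 18 (11 over the list alone, median -0.41, adjusted p = 0.681), with the elongases Elovl6 and Elovl5 at -1.52 ± 0.08 and -1.41 ± 0.28, malic enzyme (Me1) at -1.38 ± 0.03 and the acyl-CoA synthetase Acsl4 at -1.31 ± 0.33.

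Heat shock and ER stress had 7 higher and 6 lower of 20 (13 over the list alone, median 0.18, adjusted p = 0.439), with the chaperone Hspd1 at 1.46 ± 0.48 and the chaperonin subunit Cct6a at 1.24 ± 0.16, and with Ddit3 at -1.36 ± 0.20. The stress transcription factor Atf4 stood at 1.29 ± 0.55, a call lost without JA (0.0521). Translation initiation and tRNA ligases had 8 higher and 4 lower of 22 (13 over the list alone, median 0.44, adjusted p = 0.0975), with nucleolin (Ncl) at 1.63 ± 0.42 and Eif4ebp2, a repressor of translation, at -2.59 ± 0.08, Eif2s1 at -2.39 ± 0.92 and the alanine ligase Aars1 at -1.65 ± 0.40. The list passed without the JB array with the line in Cy3 (adjusted p = 0.0458) and on the arrays with the line in Cy5 (0.0460), so that call may follow the dye. Ribosomal proteins had 5 higher and 6 lower of 27 (7 over the list alone, adjusted p = 0.922); their median was -0.20 while camera gave the direction as up, and the 3 clones of the most changed gene, Rpl7 at -1.61 ± 0.13, ranged from -3.66 to -0.54. Rps27 at -0.75 ± 0.46, Rpl21 at 0.73 ± 0.51 and Rplp0 at 0.69 ± 0.17 passed but lost the call without JA (0.127, 0.0604 and 0.0514), and Rpl21 also without JB (0.0671), without Amy (0.109) and without either the JA or the Amy array with the line in Cy5 (0.0566 and 0.0507). Oxidative phosphorylation had 9 higher and 6 lower of 38 (14 over the list alone, median -0.05, adjusted p = 0.439), with Cox6a1 at 1.02 ± 0.13 and Ndufs4 at -1.001 ± 0.096, Ndufa4 at -0.88 ± 0.09 and Atp5pd at 0.67 ± 0.10, a call lost without JA (0.0545). The nervous system list had 4 higher and 4 lower of 17 (6 over the list alone, median -0.12, adjusted p = 0.681), with the glutamate transporter Slc1a3 at 2.44 ± 0.18 and Thy1 at -1.73 ± 0.08, Dpysl3 at 1.05 ± 0.17 and the myelin protein Mog at 0.62 ± 0.15, a call lost without Amy (0.0627) or without the JA array with the line in Cy3 (0.0622). Camera gave the direction as up for the apoptosis, nervous system and oxidative phosphorylation lists, against the sign of their medians, and for the glycolysis, oxidative stress, p53 target and epithelial adhesion lists, in which the mean was negative in all 4. Of the 4 measured genes of xenobiotic, bile acid and alcohol metabolism, too few to test, Por stood at 0.39 ± 0.05 (adjusted p = 0.0356), a call lost without JA (0.121), JB (0.0759) or Amy (0.137), or without single arrays of each line (0.0568 to 0.0878). Sult2a1 at -0.30 ± 0.28, Maoa at 0.15 ± 0.79 and Fmo1 at -0.13 ± 0.35 did not pass, and none of the 4 passed over the list alone. Without JB, Maoa stood at 0.61 and passed (adjusted p = 0.0191), and without the JB array with the line in Cy3 so did Sult2a1, at -0.56 (0.0269). That call follows the dye: Sult2a1 averaged 0.38 on the arrays with the line in Cy3 and -0.98 with the line in Cy5, where it passed as well (0.00542), and leaving out 1 array unbalances the dyes.

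**Figure D2:**
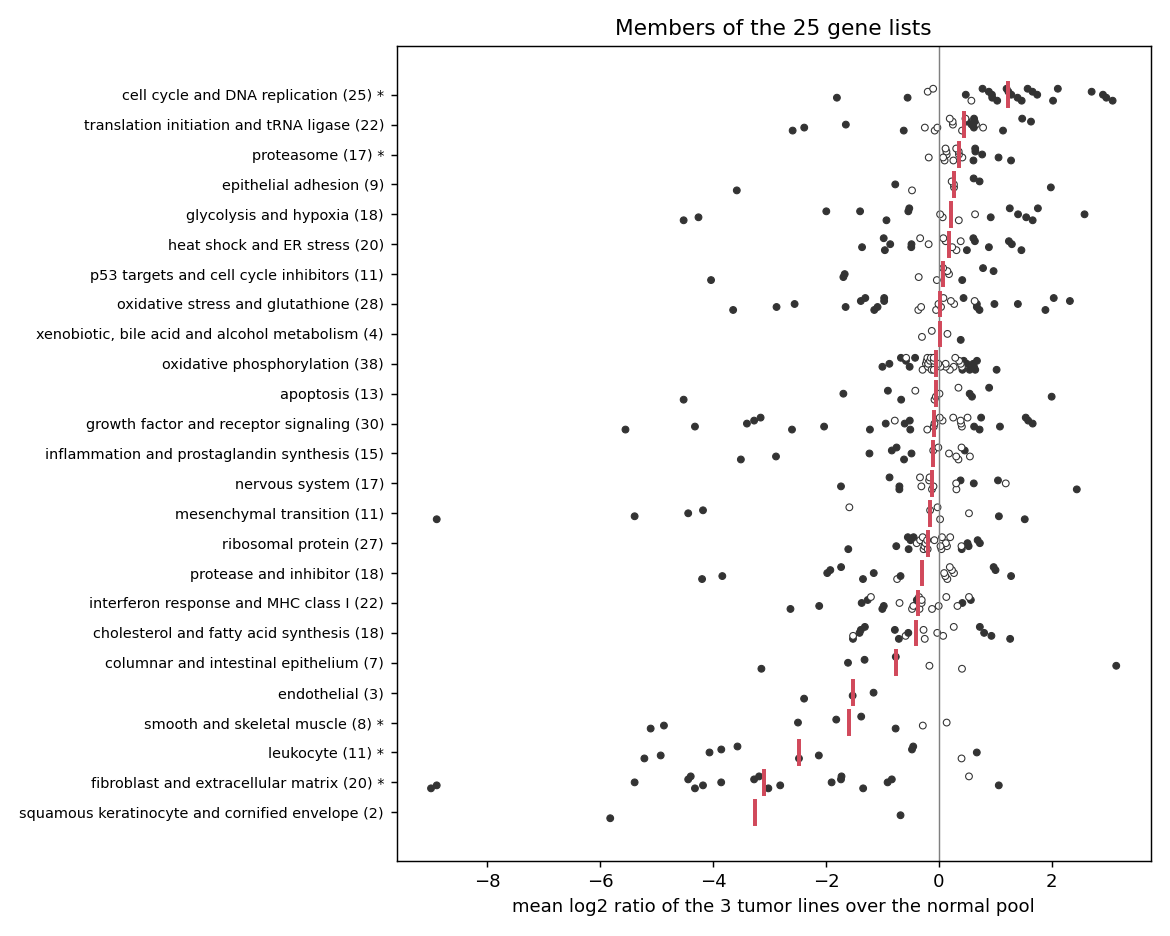
Mean log2 ratio of the 3 tumor lines over the normal pool (horizontal axis) for each measured member of the 25 gene lists, with the number measured in brackets. Filled points passed at an adjusted p under 0.05, red bars are list medians and asterisks mark the 5 lists called by camera; the cell cycle list has the highest median, 1.23, and the fibroblast list a median of -3.10.

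The second comparison took each tumor line on its own. JA had 533 features at least 2-fold higher than the pool on both arrays and 978 at least 2-fold lower, JB had 426 and 817, and Amy had 357 and 864. Features that reached this size with opposite signs on the 2 arrays numbered 42, 57 and 32. There was 1 replicate per line, so these counts have no test. JA and JB shared 289 of the higher and 665 of the lower features, JA and Amy 282 and 729, and JB and Amy 217 and 627. Independent lists of these sizes would share 31.6 and 111, 26.5 and 118, and 21.2 and 98.3. Lines simulated with no change against a common pool shared 11.3 to 11.9 on average over the draws, by pair and direction. Line means correlated across features at 0.885 for JA and JB, 0.925 for JA and Amy and 0.868 for JB and Amy, against 0.334 in the simulation; features are not independent replicates. The covariances were 1.17, 1.18 and 1.05, against 0.0453. The sign was the same in all 3 lines for 74.9% of features, against 41.3% in the simulation. Part of each excess may come from the shared pool, which could not be split.

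The third comparison asked where a line stood apart from both others by at least 2-fold in each dye orientation. JB did so for 143 features, 93 higher and 50 lower, against 26 in JA (5 higher, 21 lower) and 36 in Amy (22 higher, 14 lower). Lipoprotein lipase (Lpl) stood at 1.20 in JB against -2.54 in JA and -3.23 in Amy. The basement membrane protein Nid2 stood at 1.45 in JB against -2.84 and -2.20, the receptor tyrosine kinase Axl at 0.66 against -2.32 and -3.10, Fxyd5 at 0.71 against -2.15 and -2.59, and the G-protein regulator Rgs2 at 2.02 against -0.63 and -0.97. Genes lower in JB included the ferroxidase hephaestin (Heph), at -1.87 against 1.72 in JA and 1.79 in Amy, and the transcription factor Stat3, at -5.26 against -2.49 and -0.91. Vopp1, Wipf1 and Gnpda2 differed from the mean of the other lines by -2.63, -2.70 and -2.35 in JB. Over the 3 lines Stat3 averaged -2.89 ± 2.199 (adjusted p = 0.0309), a call lost without JA (adjusted p = 0.127).

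In Amy, Lgals7, Stat3 and Bcl10 lay above the mean of the other lines by 1.74, 2.96 and 1.48, though below the pool, and Abcc5 and Aopep by 1.502 and 1.34. Gbe1, Plpp5, Nsg1, Gng2 and the replication factor Rfc4 differed from the mean of the other lines by -1.34, -1.39, -2.35, -1.28 and -1.26 in Amy. The difference for Stat3 rests largely on its low level in JB. In JA, Cd36 and Ppp1r10 differed from that mean by 1.501 and 1.22, and Clip4, Gas7, Gad1 and Degs1 by -2.12, -1.21, -2.17 and -1.30. Cd36 lay far below the pool in every line, at -6.35 in JA, -7.69 in JB and -8.02 in Amy. Ratios of that depth may be bounds set by a dim channel. Gad1 depended on the dye orientation in every line, at 2.29 with the line in Cy3 and -1.34 in Cy5 for Amy. The arrays of a line also disagreed for Nsg1, but not in a common direction. Nsg1 stood at 0.45 and -1.21 in Amy and 2.69 and 0.77 in JB, but at 1.56 and 2.85 in JA (line in Cy3, line in Cy5). As a group, cell cycle genes were higher in JA than the mean of the other lines by a median of 0.41 and lower in Amy, with a median difference of -0.36, at percentiles 100 and 0.01 among 10000 random lists of the same size. Of 66 such comparisons, 11 lay outside percentiles 1 to 99, where 1.32 would be expected from random lists; the comparisons are not independent, since the differences of a gene sum to 0 over the lines. The others were fibroblast genes in JA at 0.29 (percentile 99.96) and in Amy at -0.26 (0.50), columnar epithelial genes in JB at 0.66 (99.91) and in JA at -0.45 (0.53), heat shock genes in JA at 0.26 (99.88) and in Amy at -0.25 (0.92), proteasome genes in Amy at -0.34 (0.13), glycolysis genes in JB at -0.22 (0.67) and ribosomal protein genes in Amy at 0.17 (99.44). The random lists hold unrelated genes, while the members of these lists were correlated (estimates of 0.18 to 0.67), so the percentiles overstate how unusual the shifts are and are no test. The random lists were also not matched on expression, for which no level was used, and a line cannot be told apart from its own arrays.

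**Figure D3:**
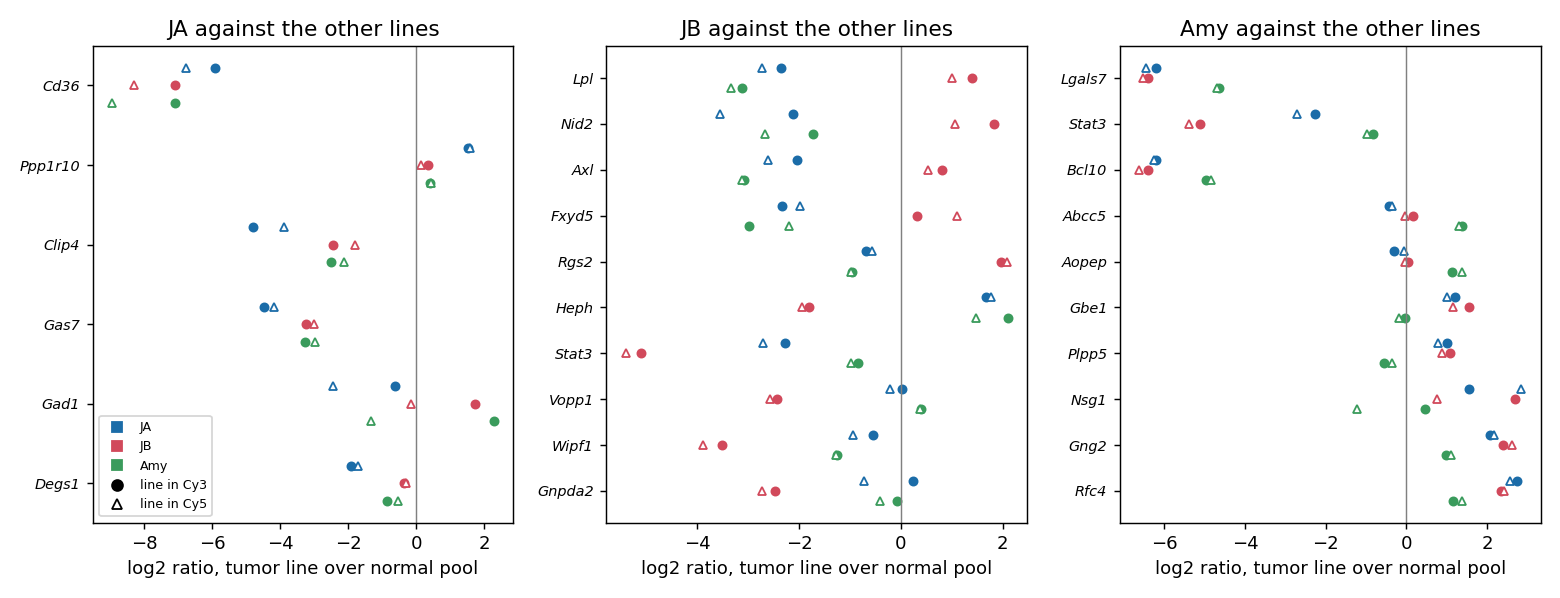
Log2 ratio of tumor line over normal pool (horizontal axis) on each of the 6 arrays for the named genes in which JA, JB or Amy stood at least 2-fold apart from both other lines in each dye orientation. Colour marks the line and shape the dye of the line; Lpl averaged 1.20 in JB, -2.54 in JA and -3.23 in Amy.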

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

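Some named genes lay above the pool on both arrays of one line and below it on both arrays of another. These differences were not tested, since each line is 1 replicate. JB exceeded JA and Amy by 3.74 and 4.43 on the log2 scale for Lpl, by 4.29 and 3.65 for Nid2, by 2.99 and 3.76 for Axl, by 2.86 and 3.30 for Fxyd5 and by 2.65 and 2.996 for Rgs2. JB lay below JA and Amy for Heph, with JA minus JB at 3.59 and Amy minus JB at 3.65, and for Maoa, at 1.41 and 1.34. Amy exceeded JB by 2.88 for Vopp1 and by 0.60 for Fmo1. Amy exceeded JA by 1.73 for Abcc5, by 1.43 for Aopep and by 0.56 for Erbb2, whose 2 clones had opposite signs. Amy lay below JA and JB for Gbe1, with differences of 1.23 and 1.46, and for Plpp5, with differences of 1.35 and 1.44.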

How the results depend on the processing

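The alternatives without tissue marker features and with the replicate block were chosen after seeing the data; the others were set before the data were examined. Of the alternatives for named genes, 2300 values kept their side of the threshold, 99 lost the call, 4 gained it and 0 reversed with a call in either setting. Values that passed in neither setting could change sign and are counted among the 2300. For example, Sult2a1 stood at -0.30 in the main test and at 0.38 on the arrays with the line in Cy3. The lost calls were 44 without moderation of the variances, 15 with the pool given the spread of 2 lines, 14 without JA, 7 without Amy and 3 without JB, and at most 3 in each of the other settings. The count of 3843 features stayed within 1.5 times for all settings except these: 1970 (667 higher, 1303 lower) with the pool given the spread of 2 lines, 1040 (300 and 740) without moderation of the variances, 2076 (709 and 1367) without JA, and 1575 (515 and 1060) at a mean of at least 1 in size. The last is stricter by construction; for the others the cause was not tested, and the 3698 without JB and 2701 without Amy rest on as few lines as the count without JA. Leaving out 1 array gave 3306 to 3716 features and 5 to 6 gene lists. This unbalances the dyes, so calls of Actb, Mog, Por, Rpl21, Sult2a1 and the translation list that changed there may follow the dye, since each also changed in 1 dye orientation alone. One loss of Por went the other way. Without the JA array with the line in Cy3 it stood at 0.41 and lost the call (limma adjusted p = 0.0568), though it was lower on the Cy3 arrays. Centring moved the median of all features from -0.12 to 0.0020, and the medians of the apoptosis, growth factor, inflammation, nervous system and oxidative phosphorylation lists changed sign. Of the 5 lists called, 0 passed in camera with an estimated correlation, where 0 lists had an unadjusted p under 0.05. That version takes its degrees of freedom from the 3 lines, and the muscle list was lost with an estimate of -0.049, below the preset 0.01. The lost calls therefore cannot be put down to correlation between genes alone. Of the 5, 2 passed without the tissue marker features, a setting that removes 3 of the lists by construction. The fry test called 11 (1 higher, 10 lower) and lost the proteasome list (adjusted p = 0.0861). Over all alternatives the adjusted p ranged from 2.54e-09 to 0.854 for the cell cycle list, 5.93e-09 to 0.854 for the fibroblast list, 0.00194 to 0.854 for the leukocyte list, 0.00247 to 0.854 for the muscle list, 0.00103 to 0.890 for the proteasome list, 0.0458 to 0.890 for the translation list, 0.0187 to 0.946 for apoptosis and 0.0309 to 0.993 for p53 targets. It ranged from 0.00552 to 0.797 for Actb, 0.00786 to 0.390 for Cstb, 0.0105 to 0.163 for Por, 0.00555 to 0.228 for Stat3, 0.0191 to 0.912 for Maoa and 0.00542 to 0.914 for Sult2a1. In fry the apoptosis list (median -0.0535, adjusted p = 0.0187) and the p53 target list (median 0.0756, adjusted p = 0.0309) ran down where camera gave up; the cause was not tested, and fry does not compare a list with other genes. The translation list passed on the arrays with the line in Cy5 (adjusted p = 0.0460) and without JB replicate 1 (0.0458). At 1.5-fold the counts were 2752 in JA, 2344 in JB, 2438 in Amy and 737 between lines, and at 3-fold 709, 600, 578 and 50, by construction. Correlations of JA with JB, JA with Amy and JB with Amy were 0.893, 0.937 and 0.871 without features whose dye swap disagreed, 0.860, 0.907 and 0.843 with the line in Cy3, and 0.864, 0.893 and 0.840 with the line in Cy5; the cause was not tested. The alternative on missing values moved nothing, since none was missing, and has no value. With the dye orientation as a replicate block and line as a random block, 3913 features passed (1557 higher, 2356 lower) and no call of a list or named gene changed. Signal over background was not used here, so the depth of the largest ratios is unknown.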

Other observations

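The tests of explanations in this part were chosen after the results were seen, except the count of sign patterns. Marker lists for other tissues, also written after, gave a median of -2.50 over 13 skeletal muscle genes, 10 of them lower and none higher. Of these 13, 6 had first been noticed among the lowest genes (Car3, Nebl, Myoz2, Myom2, Myl11 and Des), so this median is no support. The other 7 had a median of -0.62. Carbonic anhydrase Car3 stood at -5.11, the Z-disc proteins Nebl and Myoz2 at -5.06 and -4.86, and Myom2 at -4.47. Of 3 erythrocyte genes, hemoglobin Hba-a2 stood at -4.37 and Slc4a1 at 0.60. Medians were -0.90 over 5 adipocyte genes, -0.40 over 15 kidney tubule genes and -0.14 over 10 hepatocyte genes. Of the skeletal muscle genes, 5 were also in the lists fixed before.

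The first pattern was the lower level of fibroblast, leukocyte and muscle markers in all 3 lines. Dye bias was argued against, since the medians of these lists stayed at -1.55 or below in both dye orientations. RNA of muscle, blood and connective tissue cells in the normal pool may contribute, but the test cannot decide it. Besides the 6 muscle genes first noticed among the lowest, the other 7 had a median of -0.62 with 4 lower, between the bounds set for and against it. Taking out genes because they were lowest raises the median of the 7 that remain. However, 3 of these 7, Myl1, Tnnc1 and Tnni1, were already on a fixed list, with values known when the bounds were set. The rest stood at -0.64 (Myl2), -0.62 (Ldb3), -0.20 (Pygm) and 0.07 (Trdn), so the outcome leans on genes already seen. Such RNA cannot be told apart from stromal features of the normal lines themselves or from a loss of these transcripts in the tumor lines, which was not tested. The pool is labelled as cell lines.

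The second pattern was the rise of cell cycle genes. A general shift of genes used by most cells was argued against only for ribosomal protein and oxidative phosphorylation genes, with medians of -0.20 and -0.0495. The medians of the proteasome and translation lists were higher, at 0.35 and 0.44, though below the 1.23 of the cell cycle list. The arrays were centred by an unknown method, which could hide a shift of all genes. A higher share of dividing cells in the tumor lines is a hypothesis that may account for the rise and was not tested; growth conditions were not given in the sources used here.

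The third pattern was the larger number of features that set JB apart, 143 against 26 and 36. The JB arrays were the noisier ones by several measures: the dye swap correlated at 0.815, against 0.844 in JA and 0.888 in Amy, its differences had an SD of 0.715, against 0.687 and 0.530, and 9 features passed in opposite directions in the 2 orientations, against 6 and 3. Noisier JB arrays may add to the count, but were argued against as its whole cause, since noise independent between the arrays would pass in opposite directions as often as in the same one, and the 9 came to 6.29% of the 143. By this measure the JA set was the closest to noise, with 6 opposite features beside its 26, against 3 beside 36 in Amy. A difference of the line or of its RNA preparation may remain as an explanation, and the design does not separate them.

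Turning the sign of 1 line at a time gives 4 patterns in all, too few for a share under 0.05. The real pattern, 1 of the 4, called 3843 features in limma, and each of the others called 0, with at most 44 features at an unadjusted p under 0.05. All lines were compared with the same pool, so a deviation of the pool has the same sign in every line. Turning 1 line breaks that shared sign even where the tumor lines do not differ from normal cells. The counts therefore cannot separate a change in the tumor lines from a deviation of the pool, and no conclusion was drawn from them.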
